A study of Mus musculus with 32 samples.

How the data were processed

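Expression was measured in 16 RNA samples of mouse bone marrow populations on 32 Affymetrix arrays, 1 of chip type A and 1 of chip type B per sample. Per the labels, total RNA was isolated with RNeasy columns and labelled with biotin, the sorted populations were purified by flow cytometry to an estimated purity over 90%, and the lineage-depleted marrow was prepared with an enrichment kit. The values deposited by the authors are an intensity per probe set, the signal that MAS5 computes from perfect-match and mismatch probes on a linear scale. MAS5 is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited signals had been scaled per array, since the 2% trimmed mean lay between 1500 and 1501 on all 32 arrays (highest gap within a chip type 0.0152%), and they were not rescaled. The deposited instrument records, whose unit is other (text fields written at hybridisation and scanning), gave the chip lot and scan day of each array and a written description of each sample. Detection calls and probe-level intensities were not analysed here.

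All computation from the signals onward was done anew with R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Signals under the 25th percentile of a chip type (162.3 on A, 268.1 on B) were raised to it, and values were put on the log2 scale. A probe set was tested if it exceeded the median signal of its chip type (535.3 on A, 843.8 on B) on at least 3 arrays, which left 13774 of 22626 probe sets on A and 15175 of 22411 on B. Gene names came from the reference tables alone. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed. For lists and named genes each of 13599 genes was represented by 1 probe set, chosen by a fixed rule. A fold against a population whose 3 samples all lay at the floor is given as a lower bound, and other folds as computed. The precision is limited by the number of arrays, 3 per population and chip type.

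Populations were taken from the labels. The 15 samples of the 5 populations with 3 samples entered a limma model with population as the only factor and an intensity trend in the variance prior, fitted to each chip type by itself. The sixth population, with 1 sample, was left out of the fit. Probe sets were tested in 10 comparisons and with an F test over the 5 populations, two-sided for the comparisons, with Benjamini-Hochberg adjustment over both chip types within a comparison and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 150 tests, and again with the correlation estimated per list. The 15 lists were stem cell associated, early granulocyte-monocyte progenitor, late granulocyte, monocyte-macrophage, erythroid, megakaryocyte, B lineage, T and NK lineage, dendritic cell and MHC class II, mast cell with basophil and eosinophil, stromal and endothelial, cell cycle, interferon response, immediate early and heat shock, and ribosomal protein genes. They were fixed from general knowledge before the data were examined, as were the tests, the comparisons and the rule for named genes.

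That rule took, for 6 comparisons, the 8 largest rises and 8 largest falls among genes past the threshold whose samples did not overlap between the populations. It added up to 3 members of each called list in the list's direction and the sort markers Kit and Ly6a, the latter not analysed here. For the other 4 comparisons it took 4 genes each way, and for the single sample the 8 genes farthest above and the 8 farthest below the range of the 15 other samples. The text names part of the genes so chosen, and which part was decided after the data had been seen. The ratio of 3 prime to 5 prime control signals was compared with an exact permutation test of the F statistic, counting partitions with an F as large. The single sample was described by the genes at least 1 log2 unit outside the range of all other samples and by list medians among 10000 random lists matched on signal.

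The alternatives were quantile normalization, no floor (log2 of signal plus 1), a floor at the 50th percentile, no filter, a filter at the 75th percentile, the replicate number as a block, chip lot (on chip type A alone, since the lots of chip type B set total marrow apart) or scan day as a block, only the compared populations in the fit, no variance trend, a minimum of 2-fold beside the adjusted p, the Gapdh ratio as a covariate, the mean over a gene's probe sets, other references for the single sample, and leaving out each sample in turn. Fits within 1 chip lot of chip type A and the ratio of beta actin were added after the data had been seen. So was leaving out samples for the ratio and the single sample. The fits within 1 lot refitted chip type A alone, and chip type B kept its p-values from the fit of all 15 samples. The fit was tested on simulated data with the same design. There 8% of 2-fold and 67% of 4-fold changes were called and 3 of 78 called probe sets were unchanged. Only the list given a shift passed. The preset correlation was not tested there. Across 100 probe sets on both chip types, the log2 differences of the 10 comparisons correlated between types at 0.779 to 0.936.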

Results

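Gene expression was measured in cells of mouse bone marrow on Affymetrix mouse expression arrays of chip types A and B. Each of 16 RNA samples was hybridised to 1 array of each type, which gave 32 arrays. The stem-enriched population was sorted by flow cytometry, and the instrument records describe it as lineage-negative, Sca-1-positive and cKit-positive. Sca-1 and cKit are surface proteins used to sort immature marrow cells. Sorted Sca-1-negative cKit-positive cells, called cKit-positive cells here, stand for more downstream progenitors per the labels. Sorted Sca-1-negative cKit-negative cells, called cKit-negative cells here, are thought by the submitters to lean to the lymphoid lineage. Lineage-depleted marrow, from which mature cells had been removed with antibodies, and total marrow were not sorted. Each of these 5 populations had 3 samples. A further sorted population, Sca-1-positive and cKit-negative, had 1 sample and was described without a test. Median signal per array lay between 453 and 879.9 on chip type A and between 789.9 and 1011 on chip type B, and the number of arrays limits the precision. The labels do not state whether the samples of a population came from separate animals. The p-values therefore measure the spread between samples, part of which can be technical.

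The sort was visible in the transcript of Kit, which encodes cKit. Its mean log2 signal was 12.24 ± 0.10 (SD, n = 3) in stem-enriched cells and 12.19 ± 0.13 in cKit-positive cells. Lineage-depleted cells had 11.70 ± 0.07, total marrow 10.82 ± 0.32 and cKit-negative cells 9.79 ± 0.46. With 1 cKit-negative sample at the floor, a dimmer Kit probe set was also higher in stem-enriched than in cKit-negative cells (3.74-fold, adjusted p = 0.0203) and in cKit-positive than in cKit-negative cells (3.07-fold, adjusted p = 0.039, but 0.13 without cKit-positive replicate 2). Itgam, the myeloid integrin CD11b used as a lineage marker, had a mean log2 signal of 10.31 ± 0.34 in total marrow, 9.96 ± 0.70 in cKit-negative cells, 8.57 ± 0.38 in lineage-depleted cells, 8.17 ± 0.90 in cKit-positive cells and 7.61 ± 0.28 in stem-enriched cells. Cd3e, part of the T cell receptor complex, had 10.17 ± 0.30 in cKit-negative cells, 9.75 ± 0.78 in lineage-depleted cells, 8.27 ± 0.82 in total marrow, 8.02 ± 1.00 in cKit-positive cells and 7.76 ± 0.62 in stem-enriched cells. Cd3e in cKit-negative and lineage-depleted cells did not pass against total marrow (adjusted p = 0.14 and 0.151, or 0.0349 and 0.0522 without cKit-positive replicate 2). Ptprc, which encodes CD45, had 15.25 ± 0.11 in cKit-negative cells, 15.21 ± 0.30 in total marrow, 14.28 ± 0.11 in lineage-depleted cells, 13.92 ± 0.11 in stem-enriched cells and 12.83 ± 0.695 in cKit-positive cells. Its probe set on chip type B had 13.10 ± 0.77 in cKit-negative cells and 11.77 ± 0.80 in total marrow, and neither probe set passed between these (adjusted p = 0.983 and 0.388). The transcript of Sca-1 (Ly6a) was not analysed here.

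**Figure D1:**
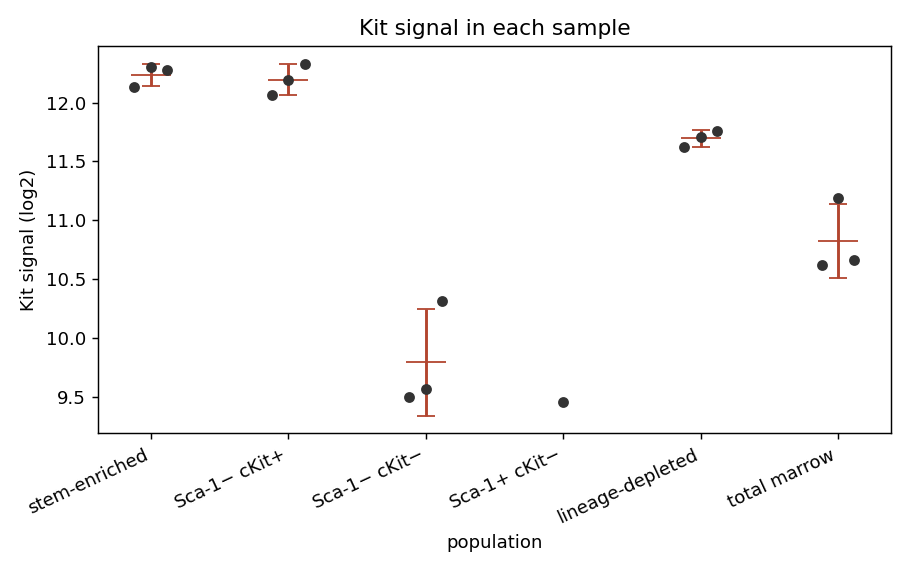
Log2 signal of Kit in each of the 16 samples by population, with the mean and SD of the 5 populations with 3 samples. Stem-enriched and cKit-positive cells lie highest, at means of 12.24 and 12.19, and cKit-negative cells lie at 9.79.

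Replicate 2 of the cKit-positive cells stood apart from every other sample. Its correlation with any other sample across probe sets lay between 0.571 and 0.69, against 0.74 to 0.934 for all other pairs of samples, where probe sets are not independent replicates. In it 534 genes lay at least 1 log2 unit above all other samples and 539 lay as far below. Its log2 ratio of the 3 prime to the 5 prime Gapdh control probe sets, a sign of how far the labelled target reached from the 3 prime end, was 0.38 on chip type A. Stem-enriched cells had the highest mean ratio, 4.00 ± 0.17 (SD, n = 3), against 3.34 ± 0.28 in lineage-depleted cells, 3.12 ± 0.33 in total marrow, 3.09 ± 0.23 in cKit-negative cells and 2.08 ± 1.49 in cKit-positive cells, or 2.93 without replicate 2. The ratio differed among the 5 populations in an exact permutation test of the F statistic over 1401400 partitions (exact p = 0.0129, and 0.0107 without cKit-positive replicate 2). The exact p was 0.011 for beta actin on chip type A and 0.0577 for Gapdh on chip type B. Leaving out stem-enriched replicate 1, 2 or 3 or cKit-negative replicate 2 moved the Gapdh permutation p to 0.0834, 0.0569, 0.0696 or 0.051.

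**Figure D2:**
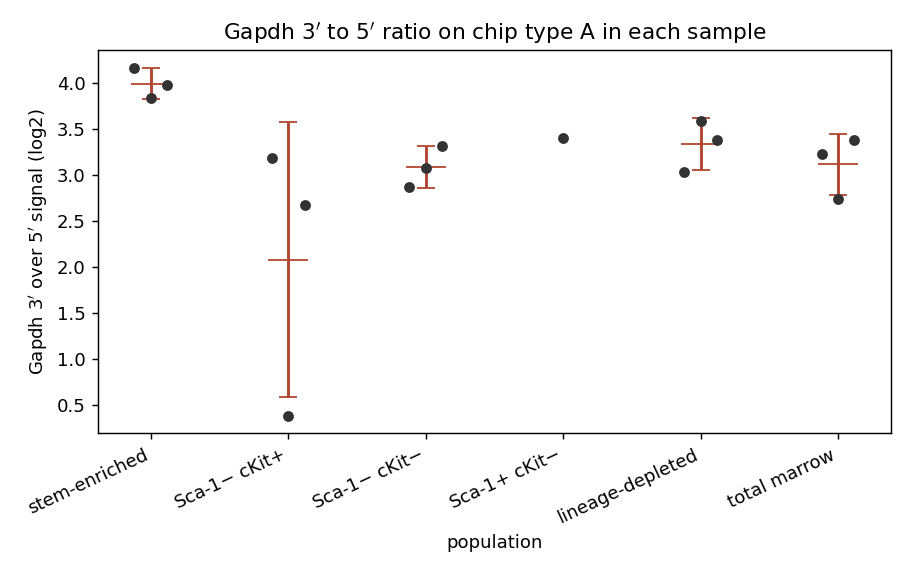
Log2 ratio of the 3 prime to the 5 prime Gapdh control signal on chip type A for each sample, with the mean and SD by population. Stem-enriched samples lie around 4.00, and cKit-positive replicate 2 lies at 0.38.

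The 5 populations with 3 samples differed widely. In limma's F test 4947 of 28949 tested probe sets (17.1%) differed among them, and 9154 had an unadjusted p under 0.05. Of 150 tests of 15 gene lists in 10 comparisons, 97 passed with the preset correlation between genes and 29 passed with an estimated correlation. The megakaryocyte list and the stromal and endothelial list passed in no comparison of this fit, with lowest camera adjusted p of 0.0663 and 0.0873. Without cKit-positive replicate 2 the stromal list was higher in stem-enriched (0.00105) and cKit-negative cells (0.0388) than in cKit-positive cells. Folds below are followed by the log2 difference ± its standard error, from limma with 3 samples per population. Meis1 and Pou2af1, whose samples overlapped between cKit-positive and cKit-negative cells, are left out of that comparison. Apart from cKit-positive and cKit-negative cells, no compared populations shared a scan day, so that scan day and population cannot be told apart.

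**Figure D3:**
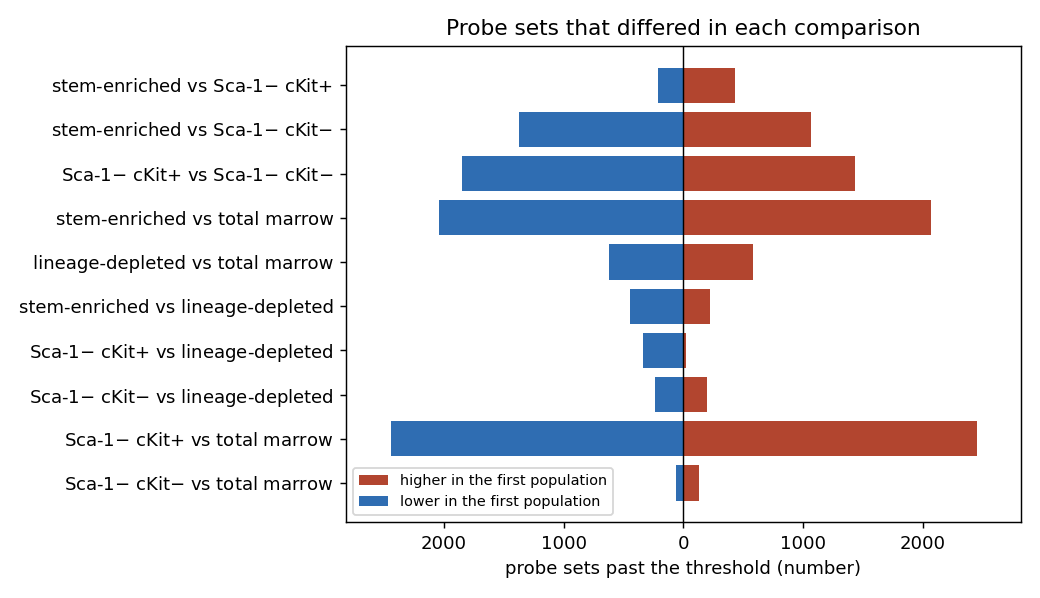
Number of probe sets higher and lower in the first population of each of the 10 comparisons at adjusted p under 0.05. The counts run from 191 in cKit-negative cells against total marrow to 4888 in cKit-positive cells against total marrow.

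**Figure D4:**
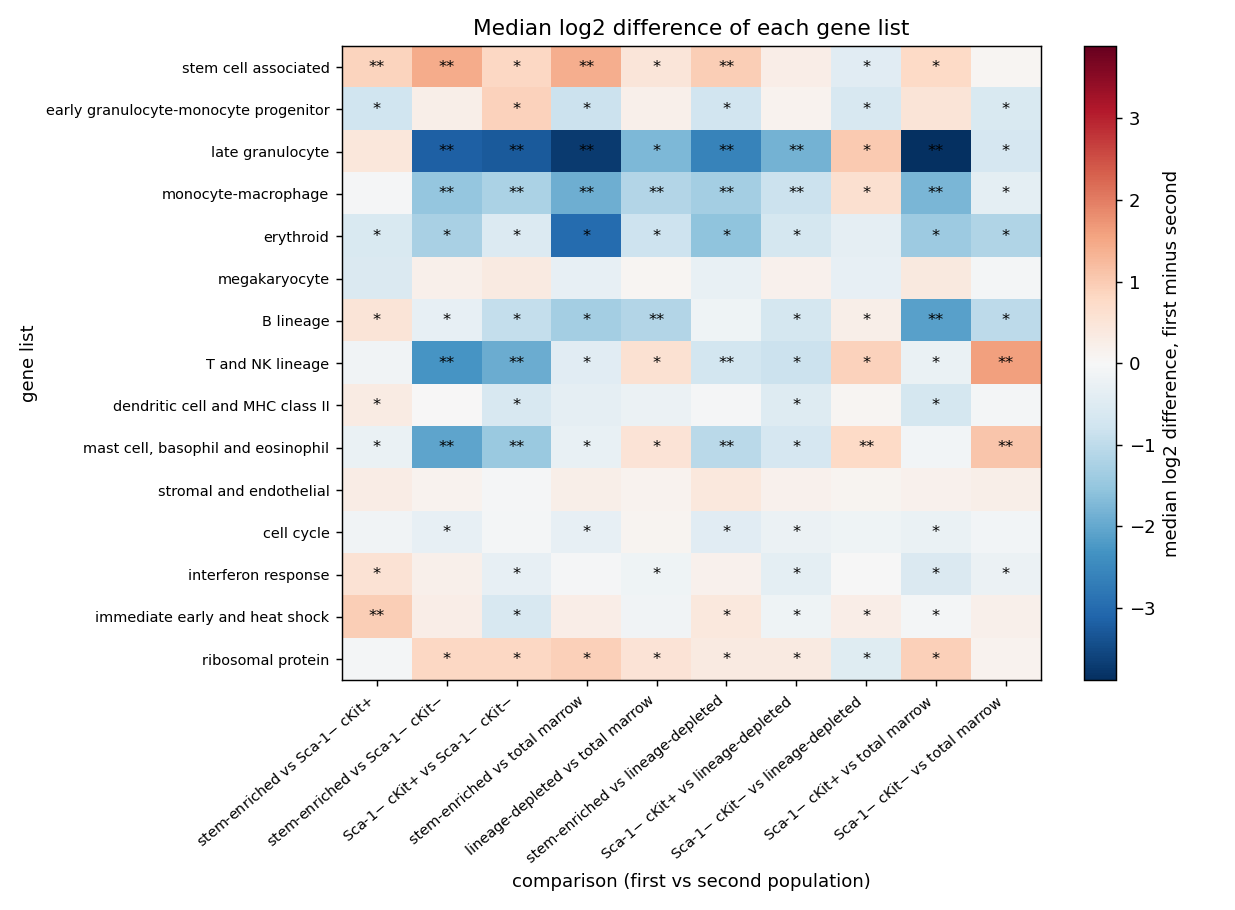
Median log2 difference of the members of each of 15 gene lists in each of 10 comparisons, with a star for an adjusted p under 0.05 and a pair of stars where it also held with an estimated correlation. The late granulocyte list has its lowest median, -3.89, in cKit-positive cells against total marrow.

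Stem-enriched cells were set against the more downstream cKit-positive progenitors to ask what marks the more primitive cells. Wfdc17, a small secreted protein of the WAP family, was 43.3-fold (5.44 ± 0.28, adjusted p = 2.21e-09) higher in stem-enriched cells. Plk2, a polo-like kinase, was 17.4-fold (4.12 ± 0.57, adjusted p = 0.00108) higher. Dusp5, a phosphatase of ERK, was 13.1-fold (3.71 ± 0.52, adjusted p = 0.000883) higher. Ctla2a and Ctla2b, which resemble the propeptides of cysteine proteases, were 8.26-fold (3.05 ± 0.35, adjusted p = 0.000261) and 9.2-fold (3.20 ± 0.40) higher. Car1, a carbonic anhydrase of red cells, was 18.9-fold (-4.24 ± 0.64, adjusted p = 0.00222) lower. The non-muscle myosin heavy chain Myh10 was 11.4-fold (-3.51 ± 0.63, adjusted p = 0.00516) lower. Zg16, a secretory granule protein, was 7.34-fold (-2.88 ± 0.39, adjusted p = 0.000969) lower. Kit did not differ detectably (log2 difference 0.04 ± 0.23, adjusted p = 0.959). Of the stem cell associated genes, 7 of 34 rose, and 17 rose adjusted over the list alone (median 0.86, adjusted p = 4.76e-09). Procr, the endothelial protein C receptor and a marker of stem cells, was 6.34-fold (2.67 ± 0.46, adjusted p = 0.00509) higher. Ltb, a lymphotoxin chain, was at least 6.25-fold (2.64 ± 0.38) higher. Of the immediate early and heat shock genes, 5 of 32 rose, and 14 rose and 1 fell adjusted over the list alone (median 0.95, adjusted p = 3.59e-08). Nr4a1, a nuclear receptor induced within minutes of stimulation, was 9.59-fold (3.26 ± 0.35, adjusted p = 0.000171) higher, and Rgs1, a regulator of G protein signalling, 4.04-fold (2.01 ± 0.37) higher. The Gapdh 3 prime to 5 prime log2 ratio stood at 4.00 and 2.08 beside these groups. Of the B lineage genes, 3 of 32 rose, and 8 rose adjusted over the list alone (median 0.50, adjusted p = 1.34e-05, adjusted p = 0.246 with an estimated correlation). Dntt, the polymerase that adds nucleotides at antigen receptor joints, was 6.61-fold (2.72 ± 0.39, adjusted p = 0.00162) higher. Of the dendritic cell and MHC class II genes, 4 of 20 rose, and 6 rose adjusted over the list alone (median 0.33, adjusted p = 0.000964, adjusted p = 0.246 with an estimated correlation). The class II chains H2-Aa and H2-Ob were 6.33-fold (2.66 ± 0.34) and 5.04-fold (2.33 ± 0.34) higher, and the cytokine receptor Flt3 4.25-fold (2.09 ± 0.37) higher. Of the interferon response genes, 4 of 31 rose, and 5 rose adjusted over the list alone (median 0.57, adjusted p = 3.34e-07, adjusted p = 0.177 with an estimated correlation). Of the early granulocyte-monocyte progenitor genes, 2 of 21 fell, and 11 fell adjusted over the list alone (median -0.76, adjusted p = 1.22e-06, adjusted p = 0.276 with an estimated correlation). Of the erythroid genes, 3 of 30 fell, and 1 rose and 9 fell adjusted over the list alone (median -0.60, adjusted p = 0.000197, adjusted p = 0.538 with an estimated correlation), Car1 among them. Of the mast cell, basophil and eosinophil genes, 3 of 20 fell, and 2 rose and 6 fell adjusted over the list alone (median -0.26, adjusted p = 0.0301, adjusted p = 0.287 with an estimated correlation). The eosinophil granule proteins Prg2 and Epx were 6.15-fold (-2.62 ± 0.46, adjusted p = 0.00553) and 4.75-fold (-2.25 ± 0.39) lower and the mast cell protease Cpa3 2.23-fold (-1.15 ± 0.19) lower. In all, 640 of 28949 probe sets passed, 427 higher and 213 lower in stem-enriched cells. Without cKit-positive replicate 2, 834 passed, among them 481 of the 640, the mast cell list did not (adjusted p = 0.247), and 3 more lists did, with medians of -0.34 for cell cycle (7.58e-05), 0.637 for stromal (0.00105) and 0.591 for late granulocyte genes (0.0327). With chip lot as a block 705 probe sets passed and the medians of the B lineage, dendritic cell and mast cell lists became 0.22, 0.18 and -0.41, while within chip lot 2 of chip type A, with 3 stem-enriched samples and cKit-positive replicates 2 and 3, 160 passed and Plk2, Zg16, Procr, Ltb, Flt3, Prg2, Epx and Cpa3 did not (adjusted p = 0.0534 for Zg16 to 0.122 for Epx). With only these 2 populations in the fit 3 probe sets passed and, of the genes named here, Wfdc17 alone (others 0.0792 for Nr4a1 to 0.277 for Epx), with the Gapdh ratio as a covariate 328, and without stem-enriched replicate 2, stem-enriched replicate 3 or cKit-positive replicate 1 233, 189 and 1227; Procr and Flt3 were lost without stem-enriched replicate 3 (0.0527 and 0.0538) and the mast cell list without stem-enriched replicate 2 (0.102) or cKit-positive replicate 1 (0.0925).

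Against cKit-negative cells, which the labels take to lean to the lymphoid lineage, stem-enriched cells had higher Meis1 and Hoxa9 transcripts. Meis1, a cofactor of Hox proteins, was 34.4-fold (5.10 ± 0.67, adjusted p = 0.000104) higher and the homeobox gene Hoxa9 13.8-fold (3.79 ± 0.53, adjusted p = 0.000214) higher. Cd34, a sialomucin of progenitors and endothelium, was 12.3-fold (3.63 ± 0.29, adjusted p = 8.63e-07) higher and Kit 5.44-fold (2.44 ± 0.23, adjusted p = 4.31e-06) higher. Alox15, a lipoxygenase, was 59.6-fold (-5.90 ± 0.40, adjusted p = 2.19e-07) lower and the chemokine Ccl6 54.5-fold (-5.77 ± 0.49, adjusted p = 1.28e-06) lower. Of the stem cell associated genes, 18 of 34 rose, and 23 rose and 1 fell adjusted over the list alone (median 1.45, adjusted p = 3.52e-14). Of the late granulocyte genes, 19 of 23 fell, and 21 fell adjusted over the list alone (median -3.16, adjusted p = 1.33e-25). Lcn2 and Ltf, lipocalin and lactoferrin of neutrophil granules, were 34.2-fold (-5.10 ± 0.42, adjusted p = 1.09e-06) and 27.4-fold (-4.78 ± 0.39) lower. Of the monocyte-macrophage genes, 15 of 23 fell, and 16 fell adjusted over the list alone (median -1.51, adjusted p = 3.05e-14). Of the T and NK lineage genes, 18 of 29 fell, and 21 fell adjusted over the list alone (median -2.31, adjusted p = 1.37e-18). The chemokine Ccl5 and the granzymes Gzma and Gzmb, proteases of cytotoxic lymphocytes, were 29.6-fold (-4.89 ± 0.53), 24.2-fold (-4.60 ± 0.52) and 12.8-fold (-3.67 ± 0.41) lower. Of the mast cell, basophil and eosinophil genes, 13 of 20 fell, and 14 fell adjusted over the list alone (median -2.05, adjusted p = 3.12e-15). The basophil protease Mcpt8 was 28.1-fold (-4.81 ± 0.27, adjusted p = 4.55e-08) lower. Of the erythroid genes, 14 of 30 fell, and 16 fell adjusted over the list alone (median -1.26, adjusted p = 1.07e-12, adjusted p = 0.215 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cell precursors, was 43.5-fold (-5.44 ± 0.55, adjusted p = 7.26e-06) lower and Slc4a1, the anion exchanger of red cells, 41.9-fold (-5.39 ± 0.50) lower. Of the ribosomal protein genes, 13 of 34 rose, and 20 rose adjusted over the list alone (median 0.80, adjusted p = 3.71e-09, adjusted p = 0.177 with an estimated correlation). Rpl37 was 3.32-fold (1.73 ± 0.39) higher. Of the B lineage genes, 1 of 32 rose and 4 fell, and 1 rose and 6 fell adjusted over the list alone (median -0.33, adjusted p = 0.0178, adjusted p = 0.55 with an estimated correlation). The signalling adaptor Bank1 was 2.8-fold (-1.48 ± 0.28) lower. Of the cell cycle genes, 1 of 49 rose and 3 fell, and 1 rose and 3 fell adjusted over the list alone (median -0.33, adjusted p = 0.000654, adjusted p = 0.553 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 was 3.78-fold (-1.92 ± 0.35, adjusted p = 0.00214) lower. In all, 2432 probe sets passed, 1063 higher and 1369 lower in stem-enriched cells, beside Gapdh ratios of 4.00 and 3.09. Leaving out cKit-positive replicate 2, which enters the shared spread, gave 4248, all 2432 among them. A block for chip lot left 2012 probe sets, the erythroid median became -0.79, the B lineage median -0.56 and the cell cycle median -0.11 (adjusted p = 0.112), the interferon list was gained (0.532, adjusted p = 0.00812), and within chip lot 2 of chip type A, with 3 and 2 samples, 998 passed and Rpl37 did not (adjusted p = 0.0961). Without stem-enriched replicate 2 or 3 or cKit-negative replicate 1 or 2 the count was 1475, 1531, 1542 or 1370, with the Gapdh ratio as a covariate 3660, Rpl37 was lost without cKit-negative replicate 2 (0.0613), the cell cycle list without cKit-negative replicate 1 (0.0567), and the B lineage list with the covariate (0.426) or without stem-enriched replicate 1 (0.051) or 2 (0.076) or cKit-negative replicate 2 (0.0984) or 3 (0.0595).

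The gates of cKit-positive and cKit-negative cells differ in cKit alone. Elane, the neutrophil elastase made early in granulocyte development, was 14.2-fold (3.82 ± 0.66, adjusted p = 0.00119) higher in cKit-positive cells. Tspan4, a tetraspanin, was 7.93-fold (2.99 ± 0.42, adjusted p = 0.000158) higher, the platelet chemokine Pf4 7.29-fold (2.87 ± 0.49, adjusted p = 0.00101) higher and the cyclophilin Ppic 7.17-fold (2.84 ± 0.26, adjusted p = 2.35e-06) higher. Kit itself was 5.28-fold (2.40 ± 0.23, adjusted p = 4.1e-06) higher and Cd34 5.77-fold (2.53 ± 0.29) higher. Alox15 was 130.2-fold (-7.02 ± 0.40, adjusted p = 2.48e-08) lower, Alas2 111-fold (-6.79 ± 0.55, adjusted p = 5.19e-07) lower and Ccl6 86.2-fold (-6.43 ± 0.49) lower. Of the early granulocyte-monocyte progenitor genes, 9 of 21 rose and 3 fell, and 10 rose and 3 fell adjusted over the list alone (median 0.91, adjusted p = 0.0123, adjusted p = 0.587 with an estimated correlation). Prtn3 and Mpo, which like Elane belong to the primary granules of neutrophils, were 4.58-fold (2.19 ± 0.43) and 4.32-fold (2.11 ± 0.38) higher. Of the stem cell associated genes, 10 of 34 rose and 1 fell, and 14 rose and 2 fell adjusted over the list alone (median 0.81, adjusted p = 0.000513, adjusted p = 0.191 with an estimated correlation). Of the ribosomal protein genes, 17 of 34 rose, and 25 rose adjusted over the list alone (median 0.79, adjusted p = 1.53e-08, adjusted p = 0.177 with an estimated correlation). Of the late granulocyte genes, 17 of 23 fell, and 18 fell adjusted over the list alone (median -3.27, adjusted p = 1.39e-22). Lcn2 was 67.9-fold (-6.09 ± 0.42, adjusted p = 1.33e-07) lower. Of the monocyte-macrophage genes, 14 of 23 fell, and 14 fell adjusted over the list alone (median -1.23, adjusted p = 7.94e-12). The lysozyme gene Lyz2 was 16.2-fold (-4.02 ± 0.28, adjusted p = 1.33e-07) lower. Of the T and NK lineage genes, 16 of 29 fell, and 1 rose and 21 fell adjusted over the list alone (median -1.92, adjusted p = 2.98e-14). Ctsw, a cathepsin of cytotoxic lymphocytes, was at least 21.1-fold (-4.40 ± 0.44, adjusted p = 5.67e-06) lower. Of the mast cell, basophil and eosinophil genes, 10 of 20 fell, and 14 fell adjusted over the list alone (median -1.46, adjusted p = 6.72e-10). Of the B lineage genes, 9 of 32 fell, and 1 rose and 12 fell adjusted over the list alone (median -0.92, adjusted p = 1.83e-07, adjusted p = 0.177 with an estimated correlation), and Bank1 was 4.04-fold (-2.01 ± 0.28) lower. Of the dendritic cell and MHC class II genes, 6 of 20 fell, and 7 fell adjusted over the list alone (median -0.61, adjusted p = 5.57e-05, adjusted p = 0.177 with an estimated correlation). Of the immediate early and heat shock genes, 1 of 32 rose and 10 fell, and 1 rose and 14 fell adjusted over the list alone (median -0.61, adjusted p = 0.000863, adjusted p = 0.0998 with an estimated correlation). Of the erythroid genes, 1 of 30 rose and 6 fell, and 1 rose and 7 fell adjusted over the list alone (median -0.54, adjusted p = 0.000757, adjusted p = 0.584 with an estimated correlation). Of the interferon response genes, 1 of 31 rose and 5 fell, and 1 rose and 6 fell adjusted over the list alone (median -0.32, adjusted p = 0.0421, adjusted p = 0.587 with an estimated correlation). In all, 3273 probe sets passed, 1429 higher and 1844 lower in cKit-positive cells, beside Gapdh ratios of 2.08 and 3.09. Without cKit-positive replicate 2, 3766 passed, among them 2581 of the 3273. With chip lot as a block 2872 passed, the erythroid median became -0.23 and the interferon median -0.16 (adjusted p = 0.0632). Within lot 2 of chip type A (cKit-positive replicates 2 and 3, 2 cKit-negative samples) 1184 passed, but not Prtn3 and Mpo (0.0934 and 0.0945). A scan day block (3431) only set aside cKit-positive replicate 1 on chip type A. With only these 2 populations fitted 938 passed, and 1705 without cKit-negative replicate 2. Without cKit-negative replicate 1 the erythroid median was 0.12 (0.61). The interferon list was lost without cKit-positive replicate 3 (0.207) or cKit-negative replicate 1 (0.293), with quantile normalization (0.0753) or a stricter filter (0.139).

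Stem-enriched cells were also set against total marrow, which holds all marrow cells. Ctla2a was 38.6-fold (5.27 ± 0.35, adjusted p = 1.24e-07) higher in stem-enriched cells, Meis1 31.4-fold (4.97 ± 0.67, adjusted p = 9.14e-05) higher and Cd34 15.5-fold (3.96 ± 0.29, adjusted p = 2.64e-07) higher. Ctla2b, Myct1 and Bex1 were 18.4-fold (4.20 ± 0.40), 16.8-fold (4.07 ± 0.35) and 14.3-fold (3.84 ± 0.36) higher, and Kit 2.66-fold (1.41 ± 0.23, adjusted p = 0.000623) higher. Slc4a1 was 122-fold (-6.94 ± 0.50, adjusted p = 2.59e-07) lower and Alas2 114-fold (-6.84 ± 0.55, adjusted p = 5.96e-07) lower. Cd177, a surface protein of neutrophils, and the gelatinase Mmp9 were 55.7-fold (-5.80 ± 0.46) and 50.3-fold (-5.65 ± 0.61) lower. Of the stem cell associated genes, 21 of 34 rose and 1 fell, and 26 rose and 1 fell adjusted over the list alone (median 1.40, adjusted p = 1.2e-11). Of the late granulocyte genes, 23 of 23 fell, and 23 fell adjusted over the list alone (median -3.74, adjusted p = 3.65e-29). Of the monocyte-macrophage genes, 15 of 23 fell, and 19 fell adjusted over the list alone (median -1.89, adjusted p = 9.1e-18). Of the erythroid genes, 28 of 30 fell, and 28 fell adjusted over the list alone (median -3.00, adjusted p = 1.83e-22, adjusted p = 0.0998 with an estimated correlation). Of the B lineage genes, 1 of 32 rose and 17 fell, and 1 rose and 22 fell adjusted over the list alone (median -1.32, adjusted p = 5.04e-11, adjusted p = 0.0998 with an estimated correlation). Of the cell cycle genes, 1 of 49 rose and 12 fell, and 1 rose and 14 fell adjusted over the list alone (median -0.32, adjusted p = 0.000179, adjusted p = 0.531 with an estimated correlation). Of the early granulocyte-monocyte progenitor genes, 1 of 21 rose and 7 fell, and 2 rose and 8 fell adjusted over the list alone (median -0.84, adjusted p = 0.00337, adjusted p = 0.538 with an estimated correlation). Of the T and NK lineage genes, 1 of 29 rose and 6 fell, and 1 rose and 10 fell adjusted over the list alone (median -0.45, adjusted p = 0.00237, adjusted p = 0.33 with an estimated correlation). Of the mast cell, basophil and eosinophil genes, 6 of 20 fell, and 3 rose and 7 fell adjusted over the list alone (median -0.28, adjusted p = 0.0128, adjusted p = 0.232 with an estimated correlation), with Prg2 12.9-fold (-3.69 ± 0.46) and Alox15 12.2-fold (-3.61 ± 0.40) lower. Of the ribosomal protein genes, 20 of 34 rose, and 24 rose adjusted over the list alone (median 0.93, adjusted p = 8.73e-09, adjusted p = 0.177 with an estimated correlation). Rpl37 was 3.78-fold (1.92 ± 0.39) higher. In all, 4108 probe sets passed, 2069 higher and 2039 lower in stem-enriched cells, beside Gapdh ratios of 4.00 and 3.12. Leaving out cKit-positive replicate 2 gave 6273, all 4108 among them. No chip lot held both populations, and with chip lot as a block 1780 passed, Kit and Rpl37 did not (adjusted p = 0.0746 and 0.235), the medians became -1.50 for the erythroid list, -0.84 for the T and NK list, -0.43 for the mast cell list (0.0632) and 0.01 for the cell cycle list (0.638). Without stem-enriched replicate 2 or 3 or total marrow replicate 2 or 3 the count was 2651, 2662, 2391 or 2554, the early granulocyte-monocyte list was lost without stem-enriched replicate 3 (0.0701) or with a stricter filter (0.0625) and the T and NK list with the Gapdh ratio as a covariate (0.155).

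Lineage-depleted cells against total marrow show what the removal of mature cells by antibody left. Cd34 was 5.99-fold (2.58 ± 0.29, adjusted p = 0.00115) higher in lineage-depleted cells and Tspan4 6.97-fold (2.80 ± 0.42, adjusted p = 0.00218) higher. Mcpt8 and Cpa3, proteases of basophils and mast cells, were 3.39-fold (1.76 ± 0.27, adjusted p = 0.0023) and 3.12-fold (1.64 ± 0.19) higher. Ceacam10 was 9.33-fold (-3.22 ± 0.46, adjusted p = 0.00211) lower, and Il1b, an inflammatory cytokine, 9.54-fold (-3.25 ± 0.49, adjusted p = 0.00228) lower. Fcmr, the receptor for the Fc part of IgM, was 8.83-fold (-3.14 ± 0.58, adjusted p = 0.00565) lower and Ms4a1, CD20, 6.86-fold (-2.78 ± 0.52) lower. Of the stem cell associated genes, 6 of 34 rose, and 9 rose adjusted over the list alone (median 0.47, adjusted p = 0.000462, adjusted p = 0.189 with an estimated correlation). Of the late granulocyte genes, 16 of 23 fell, and 19 fell adjusted over the list alone (median -1.73, adjusted p = 1.03e-18, adjusted p = 0.0545 with an estimated correlation). Of the monocyte-macrophage genes, 4 of 23 fell, and 11 fell adjusted over the list alone (median -1.13, adjusted p = 3.28e-11). Of the B lineage genes, 12 of 32 fell, and 1 rose and 18 fell adjusted over the list alone (median -1.14, adjusted p = 1.7e-15). Of the erythroid genes, 3 of 30 fell, and 8 fell adjusted over the list alone (median -0.80, adjusted p = 2.03e-07, adjusted p = 0.364 with an estimated correlation). Bpgm, which makes the red cell metabolite bisphosphoglycerate, was 6.76-fold (-2.76 ± 0.41) lower. Of the mast cell, basophil and eosinophil genes, 4 of 20 rose, and 4 rose adjusted over the list alone (median 0.53, adjusted p = 0.00337, adjusted p = 0.177 with an estimated correlation). Of the T and NK lineage genes, 2 of 29 rose, and 4 rose and 1 fell adjusted over the list alone (median 0.58, adjusted p = 0.00156, adjusted p = 0.312 with an estimated correlation). Of the ribosomal protein genes, 3 of 34 rose, and 12 rose adjusted over the list alone (median 0.54, adjusted p = 2.82e-06, adjusted p = 0.249 with an estimated correlation). Of the interferon response genes, 2 of 31 rose and 4 fell, and 3 rose and 4 fell adjusted over the list alone (median -0.16, adjusted p = 0.0487, adjusted p = 0.592 with an estimated correlation). In all, 1202 probe sets passed, 580 higher and 622 lower in lineage-depleted cells, beside Gapdh ratios of 3.34 and 3.12. Without cKit-positive replicate 2 in the shared spread 2762 passed, all 1202 among them. With chip lot as a block 551 passed, and the erythroid and interferon medians became -1.28 and -0.34. The T and NK list was lost (cameraPR adjusted p = 0.0798). Chip lot 3 of chip type A, the only one with both populations, held 1 lineage-depleted sample. For chip type A a count within it rests on that sample. Without total marrow replicate 2 or 3 or lineage-depleted replicate 1, 2 or 3 the count was 364, 300, 432, 577 or 410, with only these 2 populations in the fit 2779, with the Gapdh ratio as a covariate 2349, and the interferon list was lost without total marrow replicate 3 (0.116), stem-enriched replicate 2 (0.0509), cKit-negative replicate 2 (0.0519) or lineage-depleted replicate 2 (0.312) or 3 (0.116).

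Stem-enriched cells were further set against lineage-depleted cells, the less enriched preparation. Ctla2a and Ctla2b were 9.04-fold (3.18 ± 0.35, adjusted p = 8.61e-05) and 9.27-fold (3.21 ± 0.40, adjusted p = 0.000293) higher in stem-enriched cells, Procr 9.43-fold (3.24 ± 0.46, adjusted p = 0.000808) higher and Myct1 6.46-fold (2.69 ± 0.35) higher. Slc4a1 was 45.2-fold (-5.50 ± 0.50, adjusted p = 1.64e-05) lower, Alas2 39.8-fold (-5.31 ± 0.55, adjusted p = 5.92e-05) lower and Alox15 23.2-fold (-4.54 ± 0.40, adjusted p = 1.18e-05) lower. Among the stem cell associated genes, 7 of 34 rose, and 18 rose adjusted over the list alone (median 0.96, adjusted p = 9.97e-13). Among the immediate early and heat shock genes, 2 of 32 rose, and 4 rose adjusted over the list alone (median 0.42, adjusted p = 0.000976, adjusted p = 0.0998 with an estimated correlation). The 2 that rose were Nr4a1, 5.05-fold (2.34 ± 0.35, adjusted p = 0.00125) higher, and Rgs1, 4.09-fold (2.03 ± 0.37) higher. The Gapdh 3 prime to 5 prime log2 ratio stood at 4.00 and 3.34 beside them. Among the late granulocyte genes, 15 of 23 fell, and 18 fell adjusted over the list alone (median -2.60, adjusted p = 7.24e-23). Among the monocyte-macrophage genes, 10 of 23 fell, and 15 fell adjusted over the list alone (median -1.31, adjusted p = 8.9e-11). Among the erythroid genes, 13 of 30 fell, and 25 fell adjusted over the list alone (median -1.56, adjusted p = 7.45e-22, adjusted p = 0.104 with an estimated correlation). Among the T and NK lineage genes, 8 of 29 fell, and 13 fell adjusted over the list alone (median -0.72, adjusted p = 2.12e-11). Ccl5 was 8.83-fold (-3.14 ± 0.53) lower. Among the mast cell, basophil and eosinophil genes, 6 of 20 fell, and 10 fell adjusted over the list alone (median -1.06, adjusted p = 5.26e-10). Among the early granulocyte-monocyte progenitor genes, 1 of 21 fell, and 6 fell adjusted over the list alone (median -0.75, adjusted p = 7.12e-06, adjusted p = 0.306 with an estimated correlation). Among the cell cycle genes, 2 of 49 fell, and 4 fell adjusted over the list alone (median -0.43, adjusted p = 1.25e-07, adjusted p = 0.329 with an estimated correlation). For the ribosomal protein genes, none of 34 passed in limma, with 5 higher at unadjusted p under 0.05 (median 0.34, adjusted p = 0.000351, adjusted p = 0.38 with an estimated correlation). Kit lay 1.46-fold higher in stem-enriched cells and did not pass (0.54 ± 0.23, adjusted p = 0.29). In all, 671 probe sets passed, 226 higher and 445 lower in stem-enriched cells. Leaving out cKit-positive replicate 2 gave 1500, all 671 among them. No chip lot of chip type A held both populations, and with chip lot as a block 191 passed, Procr, Nr4a1 and Ccl5 did not (adjusted p = 0.0577, 0.0926 and 0.0547), and the medians became -0.49 for the erythroid, -1.10 for the T and NK, 0.19 for the immediate early and 0.01 for the cell cycle list (0.91), while the interferon (0.495, adjusted p = 2.79e-06) and B lineage (-0.52, 0.000142) lists were gained. Without stem-enriched replicate 2 or 3 or lineage-depleted replicate 1, 2 or 3 the count was 284, 307, 306, 302 or 408, with only these 2 populations in the fit 1089 and with the Gapdh ratio as a covariate 1520.

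Between cKit-positive and lineage-depleted cells few genes were higher in the sorted cells. Prox2, a homeobox gene, was 6.62-fold (2.73 ± 0.51, adjusted p = 0.00619) higher in cKit-positive cells and Rab3gap2 4.09-fold (2.03 ± 0.40, adjusted p = 0.00908) higher. Alas2 was 101-fold (-6.66 ± 0.55, adjusted p = 2.92e-06) lower, Slc4a1 64.2-fold (-6.00 ± 0.50, adjusted p = 2.93e-06) lower, Alox15 50.7-fold (-5.66 ± 0.40, adjusted p = 7.1e-07) lower and Ccl6 30.3-fold (-4.92 ± 0.49, adjusted p = 2.13e-05) lower. Among the late granulocyte genes, 13 of 23 fell, and 17 fell adjusted over the list alone (median -1.85, adjusted p = 2.77e-24). Among the monocyte-macrophage genes, 9 of 23 fell, and 10 fell adjusted over the list alone (median -0.84, adjusted p = 1.26e-10). Among the T and NK lineage genes, 8 of 29 fell, and 12 fell adjusted over the list alone (median -0.84, adjusted p = 1.29e-09, adjusted p = 0.0703 with an estimated correlation). Among the erythroid genes, 4 of 30 fell, and 9 fell adjusted over the list alone (median -0.69, adjusted p = 1.21e-09, adjusted p = 0.284 with an estimated correlation). Among the B lineage genes, 3 of 32 fell, and 8 fell adjusted over the list alone (median -0.70, adjusted p = 1.64e-07, adjusted p = 0.177 with an estimated correlation). Among the mast cell, basophil and eosinophil genes, 3 of 20 fell, and 4 fell adjusted over the list alone (median -0.64, adjusted p = 1.91e-05, adjusted p = 0.0545 with an estimated correlation). Among the dendritic cell and MHC class II genes, 1 of 20 fell, and 4 fell adjusted over the list alone (median -0.50, adjusted p = 3.74e-05, adjusted p = 0.177 with an estimated correlation). For the cell cycle genes, none of 49 passed in limma, with 9 lower at unadjusted p under 0.05 (median -0.23, adjusted p = 0.000399, adjusted p = 0.538 with an estimated correlation). Among the interferon response genes, 1 of 31 fell, and 5 fell adjusted over the list alone (median -0.39, adjusted p = 0.00162, adjusted p = 0.38 with an estimated correlation). Among the immediate early and heat shock genes, 1 of 32 fell, and 8 fell adjusted over the list alone (median -0.15, adjusted p = 0.0167, adjusted p = 0.215 with an estimated correlation). For the ribosomal protein genes, none of 34 passed in limma, with 12 higher at unadjusted p under 0.05 (median 0.36, adjusted p = 5.57e-05, adjusted p = 0.318 with an estimated correlation). In all, 358 probe sets passed, 23 higher and 335 lower in cKit-positive cells, beside Gapdh ratios of 2.08 and 3.34. Without cKit-positive replicate 2, 404 passed, among them 291 of the 358, and the cell cycle list did not (adjusted p = 0.2). With chip lot as a block 223 passed, the erythroid median became 0.19 (adjusted p = 0.424), the cell cycle median -0.04 (0.638), the interferon median 0.11 (0.339) and the immediate early median -0.53, and chip lot 3 of chip type A, the only one with both populations, held 1 sample of each, and a count within it rests on these. With only these 2 populations in the fit 97 passed and Prox2 and Rab3gap2 did not (0.144 and 0.14), without cKit-positive replicate 1 686 and without lineage-depleted replicate 2 217 passed, Prox2 was lost with a higher floor (0.0684) or the Gapdh ratio as a covariate (0.0784) and Rab3gap2 without lineage-depleted replicate 3 (0.06).

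Lineage-depleted cells were also the reference for cKit-negative cells. Tbc1d1, a regulator of small GTPases, was at least 11.2-fold (3.49 ± 0.60, adjusted p = 0.00899) higher in cKit-negative cells and Ahr, the aryl hydrocarbon receptor, 6.37-fold (2.67 ± 0.42, adjusted p = 0.0078) higher. Tspan4 was 6.07-fold (-2.60 ± 0.42, adjusted p = 0.00815) lower and Ppic 5.12-fold (-2.36 ± 0.26, adjusted p = 0.000785) lower. Kit was 3.74-fold lower (-1.90 ± 0.23, adjusted p = 0.00183), but its dimmer probe set did not pass (log2 difference -0.584, adjusted p = 0.633). Among the mast cell, basophil and eosinophil genes, 3 of 20 rose, and 6 rose adjusted over the list alone (median 0.79, adjusted p = 7e-08). Among the T and NK lineage genes, 1 of 29 rose, and 9 rose adjusted over the list alone (median 0.89, adjusted p = 4.86e-10, adjusted p = 0.0635 with an estimated correlation). For the late granulocyte genes, none of 23 passed in limma, with 13 higher at unadjusted p under 0.05, and 12 rose adjusted over the list alone (median 1.02, adjusted p = 3.6e-08, adjusted p = 0.215 with an estimated correlation). For the monocyte-macrophage genes, none of 23 passed in limma, with 11 higher at unadjusted p under 0.05, and 9 rose adjusted over the list alone (median 0.61, adjusted p = 8.52e-06, adjusted p = 0.112 with an estimated correlation). Among the stem cell associated genes, 4 of 34 fell, and 9 fell adjusted over the list alone (median -0.44, adjusted p = 0.000151, adjusted p = 0.177 with an estimated correlation). Among the early granulocyte-monocyte progenitor genes, 4 of 21 fell, and 1 rose and 11 fell adjusted over the list alone (median -0.62, adjusted p = 0.00109, adjusted p = 0.484 with an estimated correlation). For the ribosomal protein genes, none of 34 passed in limma, with 13 lower at unadjusted p under 0.05 (median -0.46, adjusted p = 3.03e-05, adjusted p = 0.306 with an estimated correlation). Among the B lineage genes, 1 of 32 rose, and 1 rose adjusted over the list alone (median 0.23, adjusted p = 0.032, adjusted p = 0.587 with an estimated correlation). For the immediate early and heat shock genes, none of 32 passed in limma, with 5 higher and 1 lower at unadjusted p under 0.05, and 1 rose and 1 fell adjusted over the list alone (median 0.26, adjusted p = 0.0241, adjusted p = 0.233 with an estimated correlation). In all, 434 probe sets passed, 197 higher and 237 lower in cKit-negative cells, beside Gapdh ratios of 3.09 and 3.34. Leaving out cKit-positive replicate 2 gave 1740, all 434 among them. A block for chip lot left 95 probe sets, Ahr and Tspan4 did not pass (adjusted p = 0.0564 and 0.0672), the B lineage median became -0.13 (0.728), the immediate early list was lost (0.112), and the erythroid and cell cycle lists, uncalled before (-0.35 and -0.18, adjusted p = 0.155 and 0.242), passed the other way (0.498 and 0.097, 3.69e-05 and 0.0232), while chip lot 1 of chip type A, the only one with both populations, held 1 cKit-negative sample, and a count within it rests on that sample. Without cKit-negative replicate 1 or 2 or lineage-depleted replicate 1, 2 or 3 the count was 219, 30, 90, 122 or 57, with only these 2 populations in the fit 1138, with the Gapdh ratio as a covariate 1337 and with a stricter filter 666, and Tbc1d1, Ahr and Tspan4 were lost without cKit-negative replicate 2 (0.0783, 0.0715 and 0.0585).

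Total marrow was the reference for cKit-positive cells too. Plppr3, a membrane protein of the phospholipid phosphatase-related family, was 9.27-fold (3.21 ± 0.65, adjusted p = 0.00216) higher in cKit-positive cells, Tspan4 9.11-fold (3.19 ± 0.42, adjusted p = 6.44e-05) higher and Spout1 7.28-fold (2.86 ± 0.37) higher. Alas2 was 292-fold (-8.19 ± 0.55, adjusted p = 5.46e-08) lower, Slc4a1 174-fold (-7.44 ± 0.50, adjusted p = 5.5e-08) lower and Lcn2 109-fold (-6.77 ± 0.42, adjusted p = 2.94e-08) lower. Kit was 2.58-fold higher (1.37 ± 0.23, adjusted p = 0.000687). Among the late granulocyte genes, 23 of 23 fell, and 23 fell adjusted over the list alone (median -3.89, adjusted p = 2.53e-27). Among the B lineage genes, 1 of 32 rose and 24 fell, and 1 rose and 25 fell adjusted over the list alone (median -2.11, adjusted p = 1.83e-16). Among the monocyte-macrophage genes, 15 of 23 fell, and 20 fell adjusted over the list alone (median -1.79, adjusted p = 9.1e-16). Among the erythroid genes, 19 of 30 fell, and 20 fell adjusted over the list alone (median -1.42, adjusted p = 3.03e-12, adjusted p = 0.222 with an estimated correlation). Among the ribosomal protein genes, 22 of 34 rose, and 27 rose adjusted over the list alone (median 0.94, adjusted p = 1.6e-08, adjusted p = 0.177 with an estimated correlation). Among the stem cell associated genes, 10 of 34 rose and 2 fell, and 13 rose and 2 fell adjusted over the list alone (median 0.76, adjusted p = 0.0011, adjusted p = 0.215 with an estimated correlation). Among the interferon response genes, 2 of 31 rose and 9 fell, and 2 rose and 12 fell adjusted over the list alone (median -0.56, adjusted p = 0.00159, adjusted p = 0.38 with an estimated correlation). Among the dendritic cell and MHC class II genes, 6 of 20 fell, and 3 rose and 7 fell adjusted over the list alone (median -0.67, adjusted p = 0.00202, adjusted p = 0.28 with an estimated correlation). Among the T and NK lineage genes, 1 of 29 rose and 8 fell, and 2 rose and 8 fell adjusted over the list alone (median -0.25, adjusted p = 0.0178, adjusted p = 0.472 with an estimated correlation). Among the cell cycle genes, 5 of 49 rose and 8 fell, and 7 rose and 11 fell adjusted over the list alone (median -0.27, adjusted p = 0.0183, adjusted p = 0.649 with an estimated correlation). Among the immediate early and heat shock genes, 2 of 32 rose and 8 fell, and 3 rose and 9 fell adjusted over the list alone (median -0.07, adjusted p = 0.0462, adjusted p = 0.284 with an estimated correlation). In all, 4888 probe sets passed, 2447 higher and 2441 lower in cKit-positive cells, beside Gapdh ratios of 2.08 and 3.12. Without cKit-positive replicate 2, 5023 passed, among them 3733 of the 4888, and the cell cycle and immediate early lists did not (adjusted p = 0.354 and 0.1). With chip lot as a block 2715 passed, 1092 higher and 1623 lower, the stem cell, erythroid, T and NK and immediate early medians became 0.45, -0.84, -0.41 and -0.21 and the cell cycle list was lost (adjusted p = 0.728), while chip lot 3 of chip type A held 1 cKit-positive sample, and a count within it rests on that sample. With quantile normalization 1921 were higher and 2538 lower, with only these 2 populations in the fit 732 and 1340; without total marrow replicate 2 or 3 the count was 2921 or 2945, and the T and NK list was lost without cKit-positive replicate 1 (0.093) or 3 (0.0944) and with a higher floor (0.212).

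Last, cKit-negative cells were set against total marrow. Prkcq, the protein kinase C of T cell receptor signalling, was 12.1-fold (3.59 ± 0.45, adjusted p = 0.00186) higher in cKit-negative cells. Cd7, a surface protein of T and NK cells, was 11.8-fold (3.57 ± 0.50, adjusted p = 0.00309) higher, Ctsw 11.3-fold (3.50 ± 0.44, adjusted p = 0.00186) higher and the cytokine Il6 11.8-fold (3.56 ± 0.46, adjusted p = 0.00195) higher. Jchain, the joining chain of secreted antibodies, was 10.9-fold (-3.45 ± 0.60, adjusted p = 0.0112) lower. Among the T and NK lineage genes, 9 of 29 rose, and 22 rose and 1 fell adjusted over the list alone (median 1.59, adjusted p = 2.94e-20). Among the mast cell, basophil and eosinophil genes, 6 of 20 rose, and 9 rose adjusted over the list alone (median 1.07, adjusted p = 1.56e-15). Among the B lineage genes, 2 of 32 fell, and 10 fell adjusted over the list alone (median -1.01, adjusted p = 1.56e-14, adjusted p = 0.0545 with an estimated correlation). Among the erythroid genes, 1 of 30 fell, and 16 fell adjusted over the list alone (median -1.17, adjusted p = 2.2e-15, adjusted p = 0.177 with an estimated correlation). Among the late granulocyte genes, 4 of 23 fell, and 4 fell adjusted over the list alone (median -0.67, adjusted p = 2.65e-08, adjusted p = 0.215 with an estimated correlation). For the monocyte-macrophage genes, none of 23 passed in limma, with 1 higher and 9 lower at unadjusted p under 0.05, and 1 rose and 5 fell adjusted over the list alone (median -0.38, adjusted p = 0.00187, adjusted p = 0.246 with an estimated correlation). For the early granulocyte-monocyte progenitor genes, none of 21 passed in limma, with 1 higher and 8 lower at unadjusted p under 0.05, and 1 rose and 4 fell adjusted over the list alone (median -0.58, adjusted p = 0.000224, adjusted p = 0.41 with an estimated correlation). For the interferon response genes, none of 31 passed in limma, with 1 higher and 6 lower at unadjusted p under 0.05, and 1 rose and 4 fell adjusted over the list alone (median -0.24, adjusted p = 0.00481, adjusted p = 0.449 with an estimated correlation). Kit lay 2.04-fold lower and did not pass (-1.03 ± 0.23, adjusted p = 0.0528), but did without cKit-positive replicate 2 (adjusted p = 0.0194). In all, 191 probe sets passed, 132 higher and 59 lower in cKit-negative cells, beside Gapdh ratios of 3.09 and 3.12. Leaving out cKit-positive replicate 2 gave 733, all 191 among them. No chip lot held both populations, and with chip lot as a block 18 passed, Cd7, Il6, Ctsw and Jchain did not (adjusted p = 0.128, 0.106, 0.06 and 0.0645), the medians became -1.34 for the late granulocyte, -0.61 for the monocyte-macrophage and -0.69 for the erythroid list, and the interferon list was lost (0.143). The count was 241, 107 higher and 134 lower, without cKit-negative replicate 1, 89 or 59 without 2 or 3, 60 or 63 without total marrow replicate 2 or 3, 126 without lineage-depleted replicate 2, 115 without a floor, 376 with a higher floor, 407 with only these 2 populations in the fit and 617 with the Gapdh ratio as a covariate, and Jchain was lost without cKit-negative replicate 3 (0.0553) or total marrow replicate 2 (0.0737) or 3 (0.078).

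The single Sca-1-positive cKit-negative sample had high transcripts of lymphoid and dendritic cells. In it 81 genes lay at least 1 log2 unit above all 15 other samples and 102 lay as far below. Iglv1, an antibody light chain segment, lay 9.52-fold above the highest other sample. Ccr9, a chemokine receptor of thymocytes and plasmacytoid dendritic cells, lay 8.84-fold above it, and Siglech, a receptor of the latter, 7.73-fold. Ly6d, a marker of B cell progenitors, lay 7.64-fold and Jchain 7.03-fold above it. Nfe2, an erythroid and megakaryocyte transcription factor, lay 7.59-fold below the lowest other sample, and Ctsg, a protease of neutrophil granules, 5.91-fold. The dendritic cell and MHC class II list had a median 2.01 log2 units above the mean of the other sorted populations, with 7 of 20 members above the range of all other samples. The T and NK list had a median of 1.70, with Cd3g, Cd3d, Thy1, Il7r and Bcl11b above the range. The B lineage list had 1.48, with 5 of 32 members above the range. All 3 medians lay above those of 10000 random lists of like signal. The late granulocyte, erythroid and early granulocyte-monocyte lists had medians of -1.36, -1.07 and -0.99, below all random lists. Only total marrow shared the scan days of the sample, so batch may enter these medians. With each other sorted population alone as the reference, the medians ran from 1.49 to 2.55 for the dendritic cell list, 0.81 to 2.60 for the T and NK list and 1.08 to 1.98 for the B lineage list. They ran from -3.86 to -0.12 for the late granulocyte, -1.96 to -0.40 for the erythroid and -1.59 to -0.83 for the early granulocyte-monocyte list. Of the last list, 6 members, Mpo, Ctsg and Prtn3 among them, lay below the range. The sample had log2 signals of 9.46 for Kit and 11.59 for Cd3e.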

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

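Fits within 1 chip lot, the beta actin ratio and the leave-one-out runs of the ratio and the single sample were chosen after the data had been seen. Over all alternatives, named genes kept direction and side of the threshold in 6309 results and lost the call in 644, with 0 reversed in limma. As most were picked for passing without overlap, few could reverse. List results were unchanged in 3706, lost the call in 143, gained it in 43 and reversed in 8. Of the gains 11 were cell cycle, 8 megakaryocyte and 7 each interferon and stromal. Values of the single sample moved beyond the spread in 28 of 572. For the single sample, 8 of 15 list values moved against cKit-negative and 5 of 15 each against cKit-positive and stem-enriched cells alone. A floor at the 50th percentile moved 7 of 31. Scan day as a random block was not run, since 1 day held both cKit populations and each other replicated population had a single day per chip type.

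Leaving out 1 sample at a time gave 189 to 1227 probe sets for stem-enriched against cKit-positive cells, 1370 to 4248 against cKit-negative cells, 2391 to 6273 against total marrow and 284 to 1500 against lineage-depleted cells. The range was 1705 to 3782 for cKit-positive against cKit-negative cells, 217 to 686 against lineage-depleted cells and 2921 to 5865 against total marrow. It was 300 to 2762 for lineage-depleted cells against total marrow, and for cKit-negative cells 30 to 1740 against lineage-depleted cells and 59 to 733 against total marrow. The highest count came without cKit-positive replicate 2 or 1 in each of the 10 comparisons. The F test gave 3467 to 7113 probe sets, the lists 94 to 100 calls, the single sample 184 to 205 genes and the Gapdh ratio an exact p of 0.000154 to 0.0834. A population left with 2 samples shares the spread of the others.

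With chip lot as a block the counts against total marrow were 1780 for stem-enriched, 551 for lineage-depleted, 2715 for cKit-positive and 18 for cKit-negative cells. Against lineage-depleted cells they were 191 for stem-enriched, 223 for cKit-positive and 95 for cKit-negative cells. The block reversed the camera direction of the cell cycle list against lineage-depleted cells, with a median of 0.005 in stem-enriched, -0.035 in cKit-positive and 0.097 in cKit-negative cells, where it then passed (0.0232), and in the last also of the erythroid (0.498, passed at 3.69e-05) and B lineage (-0.132) lists. Within lot 2 of chip type A, with 3 stem-enriched, 2 cKit-positive (replicates 2 and 3) and 2 cKit-negative samples, limma called 160 and 998 for stem-enriched against cKit-positive and cKit-negative cells and 1184 between the latter. Lots 1 and 3 left an arm of 1 sample, which is assumed to vary like the others, so that their counts say nothing about stability. Within lot 1, with 1 cKit-negative and 2 lineage-depleted samples, limma called 0 between them, with 3750 at unadjusted p under 0.05. Within lot 3, with 1 lineage-depleted, 1 cKit-positive and 3 total marrow samples, it called 170 for lineage-depleted cells against total marrow and 100 and 2121 for cKit-positive cells against lineage-depleted cells and total marrow. The cause of the changes under the block was not tested.

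With only the compared populations in the fit, which leaves fewer samples for the spread, the count was 3 for stem-enriched and 938 for cKit-negative against cKit-positive cells. It was 2779 for lineage-depleted cells against total marrow, and against lineage-depleted cells 1089 for stem-enriched, 97 for cKit-positive and 1138 for cKit-negative cells. Against total marrow it was 2072 for cKit-positive and 407 for cKit-negative cells. With the Gapdh ratio as a covariate 328 and 3660 passed for stem-enriched against cKit-positive and cKit-negative cells, 2349 for lineage-depleted cells against total marrow, 1520 and 1337 for stem-enriched and cKit-negative against lineage-depleted cells, and 617 for cKit-negative cells against total marrow. The covariate turned the T and NK median of stem-enriched against cKit-positive cells to 0.466 and the stromal median of cKit-positive against lineage-depleted cells to -0.397, which a filter at the 75th percentile also turned, to -1.07. The cause was not tested.

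For cKit-negative cells against total marrow 115 passed without a floor and 376 with a floor at the 50th percentile, which left 118 genes of the single sample outside the range. For cKit-negative against lineage-depleted cells 666 passed with the 75th percentile filter. An estimated correlation left 29 list calls, and the ratio on chip type B had an exact p of 0.0577. The labels do not say what a replicate number shares. After removal of the population means, 30 pairs of samples with 1 number had correlations across probe sets of -0.083 to 0.119, 1 over 0.1, against -0.093 to 0.091 for other pairs. Of 15 samples 9 correlated best, among other populations, with a sample of their own number, a hint that leaves a shared source open. With the number as a block all counts stayed within 1.5 times, at 593 for stem-enriched against cKit-positive cells, where the megakaryocyte list was gained (0.0299). Quantile normalization moved the median of all genes by more than 0.1 only for cKit-positive cells against total marrow, from 0.153 to 0.04. The cause was not tested.

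Over the alternatives, fits within 1 lot apart, the share of higher calls was 59.5 to 100% for stem-enriched against cKit-positive cells, 37.2 to 49.2% against cKit-negative cells, 39.6 to 54.7% against total marrow and 19.9 to 44.8% against lineage-depleted cells. It was 25.7 to 48.8%, 0 to 14.8% and 35.3 to 52.2% for cKit-positive against cKit-negative cells, lineage-depleted cells and total marrow. It was 26.7 to 57.6% and 44.4 to 87.3% for cKit-negative cells against lineage-depleted cells and total marrow, and 36.1 to 54% for lineage-depleted cells against total marrow.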

Other observations

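Of the tests in this part, those of an array failure, of sorting, of scan day, of chip lot and of a loss of other cells were chosen after the result had been seen, as was the weight given to signals near the floor, to sorting of both populations and to the spread of the NK and T cell genes. In cKit-negative cells against total marrow, of 8 T cell genes Cd3d, Cd3g, Thy1 and Skap1 passed (log2 differences 2.32 ± 0.33, 1.75 ± 0.31, 1.67 ± 0.37 and 1.66 ± 0.33, adjusted p = 0.00309, 0.0127, 0.0484 and 0.0207). The lowest, Trat1, differed by -0.26. Of 9 NK cell genes 0 passed in limma (adjusted p = 0.15 to 0.962), while 8 had an unadjusted p under 0.05. Their log2 differences ran from 0.08 for Nkg7 to 1.63 for Tbx21.

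Replicate 2 of the cKit-positive cells stood apart on both chip types. Failure of the array of 1 chip type is argued against, since the deviation of this sample over the probe sets on both chip types had a correlation of 0.89 between them. Labelled target reaching farther from the 3 prime end stays open. Its Gapdh ratio was the lowest of all samples on both chip types (0.38 and 0.176, next 2.68 and 2.62), and its beta actin ratio was the lowest on chip type B (1.173, next 1.231) and the second lowest on A (1.229). Of 4 ratios of the transferrin receptor and pyruvate carboxylase controls 0 were lowest in it. Ranked highest was the transferrin receptor on B (2.4, 14 lower). The only ratio with both signals at least 2-fold over the floor, pyruvate carboxylase on B (-0.06), had 3 lower. The bound set beforehand was missed but judged unsuited. RNA from cells of 1 other lineage remains possible: the highest median deviation was 1.012 log2 units, for the stromal and endothelial list, at the 68.9th percentile of random lists of like signal. Here too the bound set beforehand was unsuited, because random lists of such dim genes rose by 0.88 too, and no biological explanation was tested.

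Immediate early and heat shock genes were higher in stem-enriched than in cKit-positive cells. Both populations were sorted, so that a rise in every sorted population would cancel between them, and the test of it decides nothing. Against unsorted total marrow the median was -0.072 in cKit-positive cells (2 rose and 8 fell), 0.199 in cKit-negative cells (2 rose) and 0.258 in stem-enriched cells (6 rose and 2 fell), and the first list passed but not the others (adjusted p = 0.0462, 0.219 and 0.204). With chip lot of chip type A as a block the medians were -0.206, 0.188 and 0.01 (0.0158, 0.277 and 0.277). Scan day could account for the difference and stays open, because the populations shared 0 scan days. The populations themselves, which the sort made to differ, also stay open, as untested.

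T, NK and mast cell transcripts were higher in cKit-negative cells than in total marrow (medians 1.59 and 1.07). Loss of granulocytes, B and erythroid cells raising all other markers alike stays open. The megakaryocyte, dendritic, stem cell and stromal medians were at most 0.23, but a gate without cKit and Sca-1 may itself lower them. Chip lot of chip type A as the whole cause is argued against. With it as a block the medians over members on chip type A were 1.29 for 26 T and NK genes and 1.196 for 20 mast cell genes. Both lists passed over these members (cameraPR p adjusted over both lists = 5.79e-12 and 6.96e-17), although 18 probe sets passed in place of 191. No lot held both populations, so that this block compared them through 1 cKit-positive and 1 lineage-depleted sample on the lot of total marrow. Chip lot of chip type B cannot be told apart from the populations, which shared 0 of its lots. Whether NK rather than T cells, which the gate may deplete, were the source stays open. The NK median lay 0.3 above the T median (1.47 and 1.17, standard error 0.456). The bound set beforehand was missed but judged too narrow. The sublists left out called genes such as Ctsw. The gate, lineage-negative and lymphoid-leaning per the labels, could raise T and NK genes or deplete T cells. It was not tested.

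In limma 4947 probe sets differed among the 5 populations. Of 100 regroupings of the 15 samples, the real one included, 1 gave as many (highest other 528). This argues against chance, but not against scan day. For each comparison, the 10 splits of its 6 samples in the fit of all 15 are too few for a share under 0.05. Only the real split gave as many. For stem-enriched cells the real count and the highest other were 640 and 53 against cKit-positive cells, 2432 and 1 against cKit-negative cells, 4108 and 0 against total marrow and 671 and 2 against lineage-depleted cells. For cKit-positive cells they were 3273 and 1 against cKit-negative cells, 358 and 1 against lineage-depleted cells and 4888 and 0 against total marrow. For cKit-negative cells they were 434 and 1 against lineage-depleted cells and 191 and 0 against total marrow, and for lineage-depleted cells 1202 and 0 against total marrow.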
